A study of Daphnia magna with 6 samples.

How the data were processed

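Whole-genome bisulfite libraries of 6 pools of Daphnia magna (3 control diet, 3 Microcystis diet; 80 animals each, 5 days old) were analysed from the deposited call files. Per the labels' protocols, DNA of whole bodies was fragmented, ligated to methylated adapters and treated with bisulfite before sequencing. Whole bodies include the gut and its contents. The submitters' processing notes name CASAVA 1.5, Trim Galore 0.3.2, Bowtie2 2.1.0 and Bismark 0.9.0, a bisulfite read aligner and methylation caller. The genome build, the removal of duplicate reads, the trimming of read ends and any filter on calls are not given in the sources used here. No unmethylated spike-in was used here, so that the conversion rate was judged from CHH calls only.

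For each library the authors deposited 6 tables, 1 for each strand and context (CpG, CHG, CHH), which list a scaffold, a position, a count of methylated calls and a count of unmethylated calls. The values are counts of calls with no normalization and no header. Positions start at 1 and were used as given. In 12 of the 36 files, all of Microcystis replicates 2 and 3, 1 row named no scaffold and held no call, and was left out. A share of 1.22% of cytosine positions was listed under more than 1 context or strand, and such positions were kept as listed. A bottom strand CpG position is the top strand position plus 1, and calls of both strands were added to give 1 value per CpG site.

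Levels are methylated calls divided by all calls. The global level per context used every call. A library's 95% Wilson interval of the global level was narrow, for example 0.807 to 0.809% for CpG in control replicate 1, and covers counting error only, since reads without molecular identifiers are not independent molecules. Methylated sites were called per library by a one-sided binomial test against the library's CHH level at sites with at least 5 calls, with Benjamini-Hochberg adjustment at 0.05. On simulated data 99.1% of sites at a level of 50% were called, with 3.17 false calls among 100000 sites. Values per library were compared between diets by a two-sided exact permutation test (10 distinct splits of 6 libraries, smallest p 0.1).

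Sites and tiles were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test on methylated and unmethylated counts with 1 term per library and no trend in the dispersion, and Benjamini-Hochberg adjustment at 0.05. Sites had at least 5 calls in each library and a level over all libraries of at least 0.1 and below 1. Tiles of 1000 bp had at least 5 CpG sites with calls in every library and a level of at least 0.02. The test was run on simulated data drawn from the real coverage and levels with 200 changed features of 39606 sites and of 10432 tiles. It made 1 false call among sites and 10 among tiles. Alternatives used limma 3.58.1, quasi-binomial regression and Fisher's exact test, other coverage minimums, level filters, tile sizes and strands, and each library left out in turn. Per-library tables and exact tests were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

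The named sites were the 5 with the smallest p in each direction and the named tiles the 3 with the smallest p in each direction. This rule was fixed before the data were examined. So were the tests between diets of global levels, called sites, single sites and tiles, with their filters and most alternatives. The CHH level near methylated CpG sites and the relation of CpG to CHH levels were not part of that plan. Neither were the sites called in only 3 libraries, the clusters, the base composition and the strand agreement. The mean level of methylated sites, the counts at an unadjusted p under 0.05, and the alternative that leaves out contigs whose depth varies between libraries were added after the data had been seen. Library pairs were checked for duplicates: the variance of site differences within a diet was 0.990 to 1.06 times the counting variance and between diets 1.06 to 1.10 times, with Pearson r of 0.919 to 0.930 and 0.915 to 0.929, and no pair stood apart as a copy. The labels name each pool a biological replicate, and each was kept as one.

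Differentially methylated genes, levels by genomic feature, levels of gene lists, and the amino acids of codons with methylated or differentially methylated sites, to which the series title refers, were planned and not analysed here. They need the genome and annotation of the scaffolds in the files, and the gene table used here names another assembly with other sequence names.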

Results

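Cytosine methylation was measured by whole-genome bisulfite sequencing in whole bodies of the water flea Daphnia magna, clone Xinb3, at 5 days of age. Bisulfite turns unmethylated cytosine into a base read as T, so each read gives a methylated or an unmethylated call at each cytosine that it covers. Animals were fed green algae and cryptomonads (control diet) or a diet of which 50% was the cyanobacterium Microcystis aeruginosa, many strains of which make toxins. Each diet had 3 libraries, and each library was made from a pool of 80 animals described as a biological replicate. The libraries held between 178106916 and 203434100 CpG calls. The median cytosine in CpG context had 13 to 15 calls per library. Calls lay on 3404 scaffolds and 34789 contigs with a summed length of 130.5 Mb, at 4544491 CpG sites, of which 97.5% had calls on both strands.

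The first question was whether the diet went with a different overall amount of cytosine methylation. Methylation was rare and was found in CpG context: 0.868% ± 0.0548 of CpG calls were methylated on the control diet and 0.881% ± 0.0789 on the Microcystis diet (SD, n = 3 each). In CHG context the levels were 0.341% ± 0.0595 and 0.319% ± 0.0467, and in CHH context 0.381% ± 0.0716 and 0.355% ± 0.0499, where H is any base but G. None of the 3 contexts differed by more than the spread between libraries. The differences between the diets, Microcystis minus control, were 0.0122, -0.0217 and -0.0267 percentage points (two-sided exact permutation tests over libraries, p = 0.8, 0.5 and 0.5; n = 3 each). With 3 libraries against 3 the smallest p this test allows is 0.1. The sign of the CpG difference turned without control replicate 1 (-0.0179 points) and without Microcystis replicate 1 (-0.0206 points), and those of CHG and CHH without Microcystis replicate 3 (0.00508 and 0.00190 points).

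**Figure D1:**
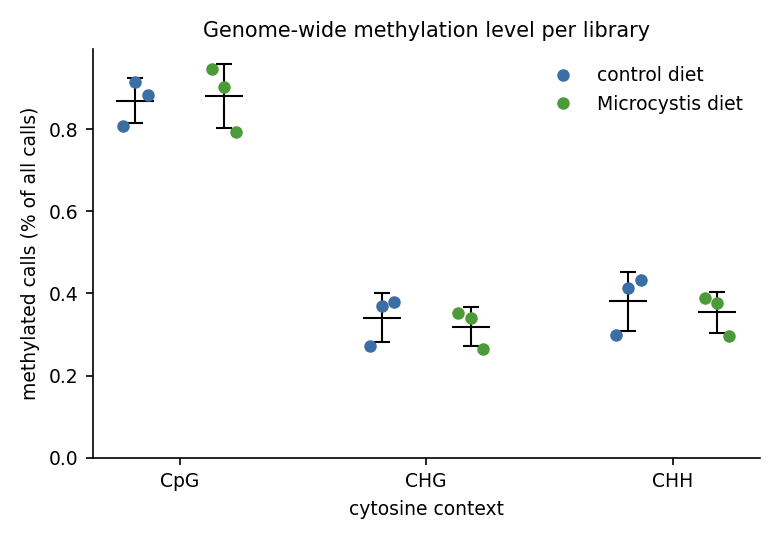
Share of methylated calls among all calls (percent, vertical axis) in CpG, CHG and CHH context (horizontal axis) for the 3 control diet and 3 Microcystis diet libraries (points), with mean and SD (bars). CpG levels lie between 0.793 and 0.946%, CHG and CHH levels between 0.266 and 0.432%, and the diets overlap in each context.

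The CHH level includes cytosines that bisulfite failed to convert and served as each library's background. It ranged from 0.297% in Microcystis replicate 3 to 0.432% in control replicate 3. Across the 6 libraries the CpG level had a Pearson r of 0.823 with the CHH level (exact permutation p = 0.103, two-sided) and a Spearman rho of 0.6 (exact permutation p = 0.242). Without the 2 libraries farthest from the median CHH level, control replicate 1 and Microcystis replicate 3, r was -0.547 over the other 4, whose range of CHH levels is narrower by this choice, so whether the levels are related stays open. After subtraction of the CHH level, 0.487% ± 0.0323 of CpG calls remained on the control diet and 0.526% ± 0.0308 on the Microcystis diet (SD, n = 3 each; exact permutation p = 0.3, two-sided).

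The next question was which CpG sites carried the methylation and whether the diets shared them. A small and stable set of sites was strongly methylated in both diets. Of 4180482 CpG sites with at least 5 calls in each of the 6 libraries, 39971 (0.956%) had a level of at least 10% over all libraries, and 74.7% of these had a level of at least 80%. At 2232476 sites no methylated call was seen. Such a site had a median of 169 calls over the 6 libraries, which allows a level of up to 1.78%, counting error only.

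**Figure D2:**
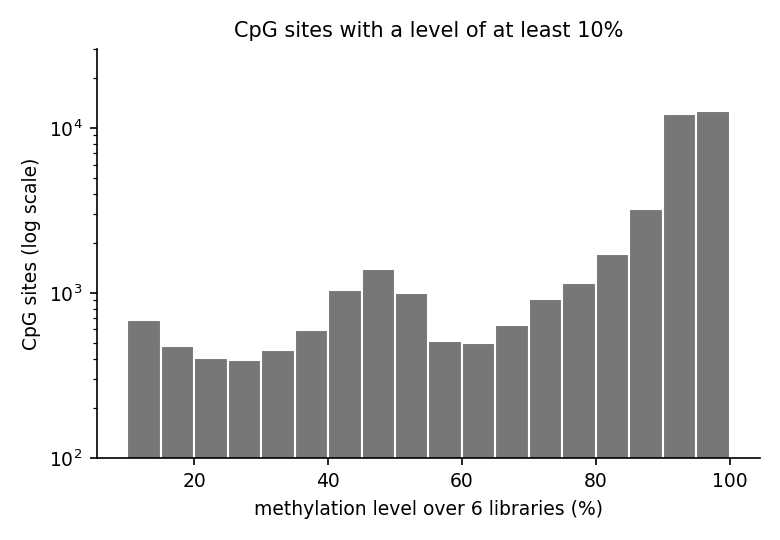
Number of CpG sites (log scale) by methylation level over the 6 libraries (percent, horizontal axis, bins of 5 points), for sites with a level of at least 10% and at least 5 calls in each library. Most sites lie above 90% (12142 sites from 90 to 95% and 12723 from 95 to 100%), and a smaller peak of 1393 sites lies from 45 to 50%.

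Tested site by site against each library's own CHH level (one-sided binomial test, Benjamini-Hochberg 0.05), 41302 ± 342 CpG sites per library were called methylated on the control diet and 41544 ± 193 on the Microcystis diet (SD, n = 3 each). The difference was 242 sites, and the diets overlapped (exact permutation p = 0.3, two-sided). It ranged from 133 to 439 sites with a library left out and was 442 with a minimum of 10 calls. The 439 came without control replicate 1, where the diets no longer overlapped (exact permutation p = 0.2, two-sided). Of the 44559 sites with enough calls in all 6 libraries that were called in any library, 39373 were called in all 6. The median level of the latter was 93.1%, against 3.26% for sites called in only some libraries. There were 15 sites called in the 3 control libraries and in no Microcystis library, and 36 with the opposite pattern. The other 18 ways to choose 3 of the 6 libraries gave 4 to 39 sites.

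Methylated CpG sites lay in short clusters in CpG-poor sequence. After a site with a level of at least 50%, the next CpG site was also at least 50% methylated in 74.1% of cases, against 0.217% after any other site. Clusters of 5 or more consecutive sites with levels of at least 20% numbered 3583. They held 63.2% of the sites with such levels and spanned a median of 411 bp. The longest clusters held 18 CpG sites. They lay on scaffold00868 from position 773040 to 773977 (89.8% ± 0.174 control, 89.9% ± 1.12 Microcystis), on scaffold02011 from 31366 to 31753 (88.9% ± 1.23 and 88.2% ± 0.373) and on scaffold02581 from 76310 to 77292 (94.9% ± 1.47 and 93.5% ± 1.40; SD, n = 3 each). In the 500 bp around a methylated site the median ratio of observed to expected CpG was 0.455, against 1.10 around a random sample of 200000 sites under 2%, and the median GC content was 37.6% against 41.6%. The strands of a CpG had nearly the same level (Pearson r = 0.955 across 38539 sites, which are not independent replicates), with a median difference of 3.31 percentage points. Among the 21 scaffolds longer than 1 Mb the share of sites with a level of at least 50% ranged from 0.657% on scaffold00915 to 1.85% on scaffold02452.

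Outside CpG, few cytosines were methylated. Among cytosines with at least 5 calls in each library, 26 of 5326446 in CHG context and 59 of 16926457 in CHH context had a level of at least 50%. CHH cytosines within 50 bp of a CpG site with a level of at least 80% were more often called methylated than CHH cytosines elsewhere, by 0.0258 ± 0.00611 percentage points (SD over 6 libraries). The difference was positive in 6 of 6 libraries (exact sign-flip permutation test, two-sided, p = 0.0312, the smallest that 6 libraries allow) and did not differ between the diets beyond the spread (exact permutation p = 0.6, two-sided). The 50 bp stretches included the cytosines of the CpG site itself. Positions listed under more than 1 context were kept, so methylated CpG calls also listed as CHH may add to the difference in every library. Base composition was not matched either, so methylation of CHH cytosines near CpG sites is not shown by this difference.

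The series title asks about methylation that differs with exposure to Microcystis, and the diets were therefore compared at each CpG site. No site passed the threshold: of 39912 sites with a level of at least 10% and below 100%, 0 had an adjusted p under 0.05 in edgeR's quasi-likelihood test (Benjamini-Hochberg; smallest adjusted p 0.125). At an unadjusted p under 0.05 there were 1917 sites (4.80% of those tested), 1282 higher and 635 lower on the Microcystis diet. The other 9 splits of the libraries into 3 and 3 gave 1455 to 1675, so the real split had the highest count of 10. Quasi-binomial regression and limma on the levels also gave 0 sites, with 358 and 2465 at an unadjusted p under 0.05, and with the replicate number as a block edgeR gave 0, with 1208. Fisher's exact test on calls summed per diet, which leaves out the spread between libraries, gave 1 site, with 1815 at an unadjusted p under 0.05. With the level filter at 0.02 edgeR gave 3 sites of 69707, each lower on the Microcystis diet (smallest adjusted p 0.000201), and 0 once contigs whose depth varied between libraries were left out (smallest adjusted p 0.860), an alternative chosen after the data had been seen. The median site had 29 calls per library, and the 95% interval of a site's difference, from counting error, had a median half-width of 7.78 points. In simulated data the test found 26% of changes of 20 points and 95% of changes of 40 points, so most smaller changes at single sites were not detectable at this depth. The SD of the differences over sites was 5.35 points, where counting error gives 5.03 points.

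**Figure D3:**
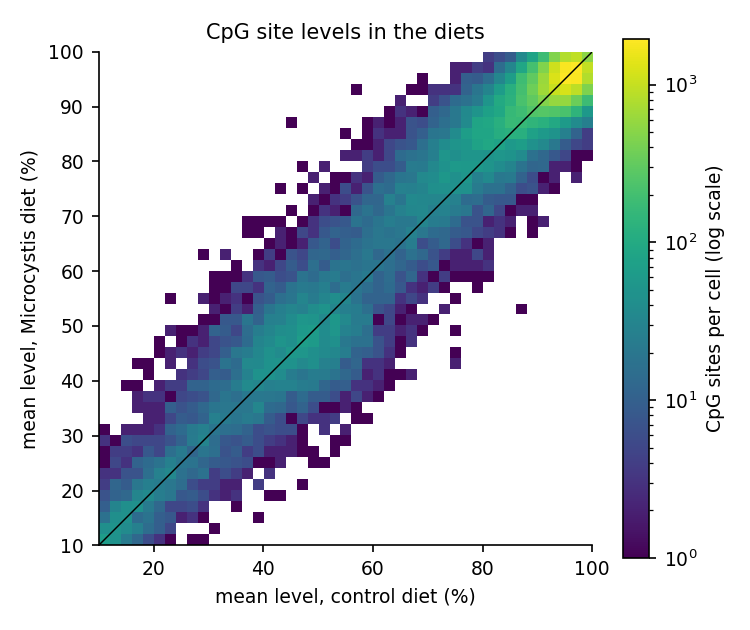
Mean methylation level of CpG sites in the control diet libraries (percent, horizontal axis) and the Microcystis diet libraries (percent, vertical axis), as the number of sites per cell of 2 by 2 points (log colour scale), for the 39615 of 39912 tested sites with both means at or above 10%. Sites follow the line of equal levels, and 218 tested sites differ by more than 20 points.

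The named sites, the 5 with the smallest p in each direction, did not pass the threshold and are given as values. The site with the smallest p lay on scaffold00944 at position 2131562, with levels of 65.04% ± 2.50 on the control diet and 74.6% ± 2.75 on the Microcystis diet (SD, n = 3 each; 401 to 481 calls per library; edgeR adjusted p = 0.125). It was the site found by Fisher's exact test (Fisher adjusted p = 0.00271; over the alternatives run its adjusted p ranged from 0.00271 to 1). Another CpG 6 bp away, at position 2131568, had levels of 75.9% ± 2.19 and 82.8% ± 3.28 (409 to 494 calls; adjusted p = 0.486). Both sites were over 10 times deeper than the median site. At 6 bp apart they are covered largely by the same reads, so the second is no separate evidence. The largest difference among the named sites was on scaffold00115 at position 298358, with 36.4% ± 9.41 and 69.1% ± 6.01 (29 to 39 calls; adjusted p = 0.340). The other named sites with higher levels on the Microcystis diet lay on scaffold00568 at position 1750666 (87.7% ± 3.34 and 100% in each library) and on scaffold00389 at position 936241 (89.9% ± 1.65 and 99.3% ± 1.13).

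Among sites with lower levels on the Microcystis diet, the one on scaffold01581 at position 2893 had 24.3% ± 2.19 on the control diet and 9.36% ± 1.62 on the Microcystis diet (64 to 86 calls; adjusted p = 0.486), and the one on scaffold02663 at position 3047 had 81.7% ± 7.78 and 58.6% ± 6.63 (38 to 52 calls; adjusted p = 0.519; SD, n = 3 each). The remaining 3 sites were at 100% in each control library: position 256986 of scaffold01574 (91.8% ± 5.69 on the Microcystis diet), position 332560 of scaffold01348 (90.5% ± 6.80) and position 153 of contig26550 (87.3% ± 8.61). Which genes these positions lie in was not analysed here, since no annotation of the files' scaffolds was used.

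Calls were also summed over tiles of 1 kb, which raises the depth to a median of 704 calls per tile and library. No tile passed the threshold: of 10434 tiles with a level of at least 2%, 0 had an adjusted p under 0.05 in edgeR's quasi-likelihood test (smallest adjusted p 0.980). At an unadjusted p under 0.05 there were 465 tiles (4.46%), 308 higher and 157 lower on the Microcystis diet. This balance was 239 to 208 without Microcystis replicate 1 and 145 to 109 with the level filter at 0.1. Without Microcystis replicate 3 there were 735 at an unadjusted p under 0.05 and still 0 at the adjusted threshold. Quasi-binomial regression gave 0 (223 unadjusted), limma 0 (561) and edgeR with the replicate number as a block 0 (571). In simulated data that held counting error only, the test found 71% of changes of 5 points and 96% of changes of 10 points. The real libraries of a diet varied by 2.39 times the counting variance per tile, so the share found in them would be lower.

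The named tiles with the smallest p among those higher on the Microcystis diet lay on scaffold01361 from position 2372001 to 2373000 (3.35% ± 0.187 and 5.18% ± 0.568), on scaffold00683 from 1001 to 2000 (6.72% ± 1.22 and 11.8% ± 3.12) and on scaffold01253 from 347001 to 348000 (5.75% ± 0.330 and 9.29% ± 1.69; SD, n = 3 each). Among tiles lower on the Microcystis diet, the tile on scaffold00626 from 1001 to 2000 had 52.2% ± 2.57 on the control diet and 40.7% ± 2.91 on the Microcystis diet. The one on scaffold00024 from 1607001 to 1608000 had 60.2% ± 2.09 and 48.3% ± 3.63, and the one on scaffold01361 from 890001 to 891000 had 31.4% ± 4.02 and 22.5% ± 1.29. For each of these 6 tiles the adjusted p was 0.980.

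Although no single site or tile passed, the mean level of the 39912 tested sites was slightly higher on the Microcystis diet. Averaged over these sites, the level was 81.6% ± 0.129 on the control diet and 82.5% ± 0.172 on the Microcystis diet (SD, n = 3 each), a difference of 0.878 percentage points. All 3 Microcystis libraries lay above all 3 control libraries. Chance separates the diets in this way, in either direction, in 10% of cases. The exact permutation p was 0.1 (two-sided), the smallest that 3 against 3 libraries allow, so the test could not pass 0.05. This comparison was added after the data had been seen. The mean was higher on 146 of the 182 scaffolds with at least 20 such sites (80.2%), where the other 9 splits of the libraries gave 54.4 to 75.3% of scaffolds in one direction. Those splits mix the diets and keep part of any shift between them, so they do not measure chance for this share. With methylated calls divided by all calls of these sites, which gives deep sites more weight, the difference was 1.42 points and the diets overlapped (exact permutation p = 0.2, two-sided). The diets also overlapped in the mean level of each library's own called sites, a set that differs between libraries: 79.08, 80.03 and 80.26% in control replicates 1 to 3, and 80.04, 80.78 and 80.25% in Microcystis replicates 1 to 3.

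**Figure D4:**
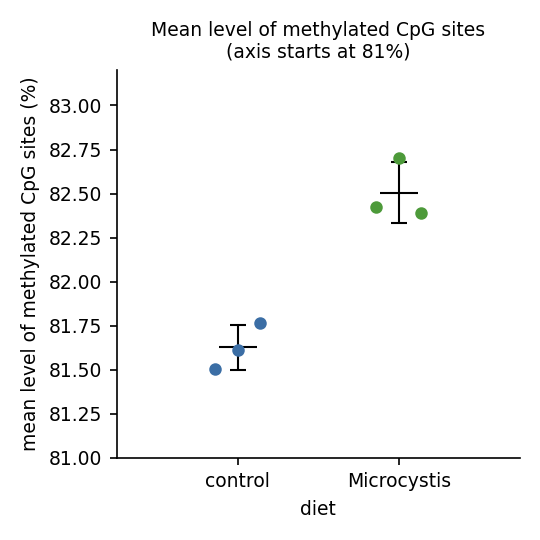
Mean methylation level of the 39912 methylated CpG sites (percent, vertical axis, starting at 81%) in each library (points) by diet (horizontal axis), with mean and SD (bars). The 3 control libraries lie between 81.5 and 81.8% and the 3 Microcystis libraries between 82.4 and 82.7%.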

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

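The alternative with contigs of variable depth left out and all alternatives of the mean level of methylated sites were chosen after the data had been seen. The CpG difference between diets (0.0122 points) took the other sign as a mean of site levels (-0.0160 points), which weights shallow sites more, and it ranged from -0.0206 to 0.0560 points with a library left out, below 0 without control replicate 1 (-0.0179) or Microcystis replicate 1 (-0.0206). CHG ranged from -0.0559 to 0.00508 and CHH from -0.0677 to 0.00190 points, above 0 only without Microcystis replicate 3. Their lowest values came without control replicate 1, where the diets no longer overlapped (exact permutation p = 0.2 for both, two-sided). The difference in methylated sites per library stayed positive under the alternatives run (133 to 439 sites with a library left out, 165 without contigs of variable depth), and so did that of the mean level (0.780 to 0.947 points with a library left out). In numbers of methylated sites the diets no longer overlapped without control replicate 1.

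Site calls were 0 with each library left out (1752 to 1835 at an unadjusted p under 0.05), 1 with Fisher's exact test and 3, each lower on the Microcystis diet, with the level filter at 0.02. Those 3, named after their values were seen, are position 346 of contig31986 (13.7% ± 6.78 control, 2.12% ± 1.05 Microcystis), 560 of contig45075 (10.3% ± 3.92 and 1.999% ± 0.458) and 391 of contig45493 (9.72% ± 3.86 and 1.53% ± 0.655; SD, n = 3 each). With contigs of variable depth left out, the filter at 0.02 gave 0 sites (edgeR; 2241 unadjusted). Tile calls were 0 under each alternative run (374 to 735 unadjusted with a library left out, against 465). Unadjusted counts also moved by over 1.5 times with quasi-binomial regression (358 sites, 223 tiles), for sites with the block (1208), where the cause was not tested, and for tiles with the level filter at 0.1 (254), where fewer tiles were tested (5660). Of the 10 named sites and 6 named tiles, 1 passed the threshold, with Fisher's exact test. They were chosen by their p, and many alternatives kept their counts, so a kept direction shows no stability. At single sites, deviations of same-numbered libraries correlated at -0.0102, 0.0121 and -0.00245. Sites varied within a diet by 1.03 times the counting variance, and tiles were not checked. These values could therefore hardly show a pairing by replicate number. With the number as a block, sites and tiles passing stayed at 0, and the block gave the global differences of 0.0122 (CpG), -0.0217 (CHG) and -0.0267 points (CHH), 242 sites and 0.878 points of mean level (exact sign-flip permutation, smallest p 0.25). Alternatives for genes, genomic features, gene lists and codons were not run. Depth limits single sites, where changes under 20 points would mostly be missed.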

Other observations

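The tests of incomplete conversion, of collapsed and heterozygous sequence, of DNA of other organisms and of other splits of the libraries were chosen after the results had been seen.

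Some sequence in the assembly changed its depth between libraries far more than the rest. Of 20794 scaffolds and contigs with at least 100 cytosines and 3000 calls, 842 had a share of a library's calls that differed at least 3 times between the lowest and the highest library, where the median was 1.38 times. They were short (median 292 bp, longest 4820 bp, 320.3 kb in all). They took 0.226% ± 0.0445 of calls on the control diet and 0.284% ± 0.0805 on the Microcystis diet (SD, n = 3 each, exact permutation p = 0.3, two-sided). The numbers deepest in Microcystis replicates 1 to 3 were 79, 332 and 279, and in control replicates 1 to 3 were 30, 1 and 121. On 218 of them all 3 Microcystis libraries lay above all 3 control libraries, and on 3 the reverse held. The longest of the 218 was scaffold01074 (3216 bp), with 0.000342% ± 0.000214 of calls on the control diet and 0.00270% ± 0.00120 on the Microcystis diet. The longest of the 3 was scaffold02946 (4558 bp), with 0.0681% ± 0.0245 of calls on the control diet and 0.0138% ± 0.00693 on the Microcystis diet (SD, n = 3 each). Scaffold02946 alone was thus a large part of the control share of 0.226%, and the shares were not compared without it.

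Of 59 CHG cytosines with a level of at least 50% and at least 30 calls, 58 lay on the scaffolds and contigs compared for depth, and 43 of those (74.1%) on the contigs of variable depth, which held 0.412% of the cytosines compared. Of these 43, 14 lay in the motif CCWGG and 18 in GCWGG, which made up 5.79% and 7.11% of CHG cytosines on the contigs. W stands for a position listed as a cytosine on neither strand, read as A or T. In CHH context there were 96, of which 95 were on sequences compared and 31 of those (32.6%) on the contigs. Of these 31, 10 lay in the motif GCCCGC (0.471% of CHH cytosines there), against 0 of the 64 elsewhere. Most of the strongly methylated cytosines on the contigs outside these motifs read GCW, in both contexts. Some lay at adjacent positions on opposite strands, such as positions 233 (CHH) and 234 (CHG) of contig24174. GCWGG may therefore be only the CHG part of a shorter motif that spans both contexts, and its share of CHG cytosines does not describe that motif. Methylated cytosines in short motifs are known from bacterial DNA methyltransferases, so DNA of bacteria in or on the pooled animals is a candidate source of the CHG signal, while the 64 CHH cytosines on contigs of steadier depth argue against it for most CHH sites. Which organisms, whether diet changed them, and whether uneven amplification adds to the depth differences stay open; the 3 sites called at the level filter of 0.02 were all on such contigs.

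The mean level of the 39912 tested CpG sites was higher in the Microcystis diet libraries by 0.878 points, although the diets overlapped in the mean level of each library's own called sites. Incomplete conversion of unmethylated cytosine does not account for it. The CHH level was too low to move levels this much, and its mean was lower on the Microcystis diet (0.355% against 0.381%). Correction for each library's CHH level could thus change little, and the difference was then 0.887 points. CHH calls do not show whether methylated cytosines were converted. Poorly covered sites do not account for the difference either, since it was 0.744 points among the 23571 sites with at least 20 calls in each library. The difference did not rest on a few scaffolds of these libraries (95% bootstrap interval over scaffolds 0.804 to 0.961 points, without the spread between libraries), and 80.2% of scaffolds were higher, although the other splits of the libraries put 54.4 to 75.3% of scaffolds on the same side. An effect of diet stays open, and so do differences in size or stage between the pools and methylation bias near read ends, which position tables cannot show. Chance stays open too, since 10 splits cannot give a share under 0.05. The highest of the other splits was 0.461 points. As the diets do not overlap in this mean, each other split had to be lower than the real one, so this value decides nothing.

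Levels of CpG sites peaked near 50% (1393 sites from 45 to 50%, 392 from 25 to 30%), and the 4332 sites from 35 to 60% with under 400 calls over the 6 libraries varied between libraries by 1.05 times the counting variance. Duplicated sequence collapsed in the assembly is not the main source, since without a depth limit the median was 173 calls both for sites from 35 to 60% and for sites of at least 80% (ratio 1), although 4.50% of the former had at least 400 calls, against 0.818% of the latter. A heterozygous base variant that removes a methylated CpG from an allele would give such a level on both strands, and the share of the 4332 sites among methylated sites rose with the density of cytosines at about 50% of their neighbours' depth (Spearman rho = 0.364 over 605 windows of 100 kb, permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give), so variants may account for part of them. In the 321 windows with no such cytosine the share was still 8.30%, against 9.92% over all windows. That is only indirect evidence against variants there. An allele with T in place of C is counted as an unmethylated call and keeps its depth. Of the 4332 sites, 48.3% had a neighbouring CpG site that also had a level near 50%. Such a neighbour lay beside 5.89% of sites of at least 80%. Both neighbours were over 80% at 4.49% of the 4332 sites, against 49.2% of sites of at least 80%. Among those in the 321 windows these shares were 48.7% and 4.18%. A variant that removes a single CpG would leave its neighbours methylated. Among the 4332 sites with methylated neighbours, these values thus argue against such variants as the main source. Both neighbours were under 10% at 16.0% of the 4332 sites, against 3.56% of sites of at least 80%. At such isolated sites the neighbours cannot show whether a variant is present. Methylation of a single allele or in part of the cells stays open and was not tested.

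Neighbouring CpG sites 4 to 63 bp from a methylated site lay at a distance divisible by 3 in 38.7% of cases (95% bootstrap interval 37.7 to 39.6%), where chance gives 33.3%. Around unmethylated sites matched on CpG number in 500 bp the share was 34.6% (34.1 to 35.1%), and around a random sample of 200000 unmethylated sites, not matched, 36.0%. The match was incomplete, with 29870 matched sites for 33762 methylated ones. It did not equalise CpG density at 4 to 63 bp, where the matched sites had 34335 pairs and the methylated sites 20331. A period of 3 bases is a mark of coding sequence, so the higher share is consistent with methylated sites lying in coding exons; the position of exons was not analysed here.

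The comparison of sites and that of tiles each gave 0 calls in edgeR's main run (1917 and 465 at an unadjusted p under 0.05) and 0 in quasi-binomial regression and limma, with 1 site in Fisher's exact test and 3 in edgeR with the level filter at 0.02 (0 without contigs of variable depth). The highest of the other splits gave 5 sites and 5 tiles. Both came from the same split, control replicates 1 and 3 with Microcystis replicate 3 against the rest. That split also gave the most tiles at an unadjusted p under 0.05 (1023). With a real count of 0 no split can give fewer, so the comparison with the other splits decides nothing, and 10 splits could not give a share under 0.05 in any case. For sites the real split had the highest unadjusted count, 1917 against 1455 to 1675 in the other splits, and for tiles it had 465 against 374 to 1023.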
